A study of Mus musculus with 9 samples.

How the data were processed

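Bone marrow RNA was sequenced from mice that had a bone fracture together with a traumatic brain injury. The 9 libraries fall into 3 groups of 3 by genotype, namely wild type (WT), knockout of Adrb2 (the beta 2 adrenergic receptor) and knockout of Adrb3 (the beta 3 adrenergic receptor). All 9 came from injured animals, so the comparisons are between genotypes and not between injured and uninjured mice. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a SMARTER mRNA-Seq kit.

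The deposited values are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), rounded by the authors to 2 decimals. Per the submitters' processing notes, FastQC, fastp, HISAT2, StringTie and edgeR were used with the mouse build mm10. Their versions, their settings, the gene annotation and the handling of reads that map to several genes are not given in the sources used here. An FPKM value is a share of a library's mapped fragments, so a rise of a few abundant genes lowers all other values. Reads shared by near-identical genes, such as immunoglobulin segments, ribosomal protein genes and their pseudogenes, can be split in ways that the table does not record. Strand was not stated either, so overlapping genes on the 2 strands cannot be separated.

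The table held 30979 rows, of which 315 were at 0 in all libraries. For 62 gene symbols with repeated rows, the row with the highest mean was kept and 68 rows were left out, which left 30911 symbols. Positions and gene types came from GENCODE M21 on GRCm38, the assembly also called mm10. A position was found by symbol for 29893 symbols and by synonym for 275, and 743 had none. Whole reads could not be recovered from the steps between low values, so read depth is unknown and no counting interval is given. Library totals ran from 344291 to 386254 FPKM, and 11952 to 12460 genes per library had at least 1 FPKM. No 2 libraries were duplicates, since at most 0.75% of values were identical in any pair.

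Before the data were examined, the tests, the filter, 37 gene lists, the rule for named genes and most alternative settings were fixed. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 12624. Values were taken as log2(FPKM + 1), with no scaling between libraries. All fold changes are on this scale, which understates the change of genes with low values. A linear model with 1 mean per genotype was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a mean-variance trend). The 3 contrasts were Adrb2 KO against WT, Adrb3 KO against WT, and Adrb2 KO against Adrb3 KO, and an F test covered any difference among genotypes. Genes were counted as past the threshold at a Benjamini-Hochberg adjusted p under 0.05. Errors given with FPKM means are SDs over 3 libraries, and those given with fold changes are standard errors from limma. All adjusted p-values of genes are from limma and are two-sided. Nothing in the labels says that the 3 libraries of a genotype came from separate animals. The p-values measure the spread between these libraries, which may be technical.

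Gene lists for marrow cell types, bone cells, stress and signalling were tested with limma's camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 33 lists with at least 5 tested members. Camera was repeated with a correlation estimated from the residuals, and fry was run as a rotation test of a net direction. For each list, members past the threshold were counted over all genes tested and again adjusted over the list alone. Adrb2 was compared by two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Genes past the threshold on the chromosome of the targeted gene, and within 10 Mb of it, were set against other genes by two-sided Fisher's exact tests. The overlap of the 2 knockouts was set against 100 simulated pairs of unchanged groups that share the WT libraries.

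Named genes followed a fixed rule. Adrb2 and Adrb3 were to be named whatever their values, and Adrb3 was not analysed here. Among genes past the threshold with a mean of at least 2 FPKM and no overlap between the libraries of the groups compared, the 8 with the largest rise, the 8 with the largest fall and the 4 with the highest mean and an absolute log2 fold change of at least 0.58 were named. Unnamed loci (Gm and Rik symbols), pseudogenes and variable segments of immunoglobulin and T-cell receptor genes were left out of these. From each gene list in the text, the 2 to 4 members with the smallest p were named.

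Simulated data held 12624 genes, and 200 genes with a mean above about 2 FPKM were changed. Recovery of genes with lower values was not measured. The Adrb2 KO against WT fit recovered 86.6% of 1.5-fold changes, 98.5% of 2-fold changes and 100% of 4-fold changes, and 4% of its calls were false. For Adrb3 KO against WT, 79.1% of 1.5-fold and 97% of 2-fold changes were recovered, with 3.7% false calls. For Adrb2 KO against Adrb3 KO, 79.1% and 98.5% were recovered, with 6.1% false calls. A simulated list shifted by a fixed amount was found in each contrast, and no other list was called. Genes were simulated independently of each other. The simulation therefore cannot show how often camera wrongly calls lists whose genes vary together.

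Alternatives covered the pseudocount, the filter on low values, scaling between libraries (the same total in every library, median-of-ratios, quantile normalization, and globin genes left out), the variance model, the threshold, the 2 compared groups alone, the replicate number as a block, and each library left out in turn. Leaving out immunoglobulin and T-cell receptor genes, and removing a trend with transcript length and GC content, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.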

Results

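The transcriptome of bone marrow was measured by RNA sequencing in 9 libraries, 3 from wild-type (WT) mice and 3 from each of 2 knockout (KO) lines, lacking Adrb2 or Adrb3. All animals had a fracture and a traumatic brain injury. Adrb2 and Adrb3 encode adrenergic receptors through which sympathetic nerves act on target cells, and the comparisons ask what the loss of each receptor changed in the marrow of injured animals. Values are FPKM. Totals per library ran from 344291 to 386254 FPKM, and read depth is unknown. The neutrophil genes S100a8 and S100a9 together held 7.88% to 9.67% of the FPKM of a library. Globin genes held 1.19% ± 0.501 (SD, n = 3) in WT, 1.73% ± 0.433 in Adrb2 KO and 1.94% ± 0.324 in Adrb3 KO. Mitochondrially encoded genes held 11.3% ± 2.43 in WT, 9.89% ± 1.48 in Adrb2 KO and 9.67% ± 0.51 in Adrb3 KO.

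Adrb2 (chromosome 18, 62177816 to 62179959, mm10) was at 12.1 ± 0.995 FPKM (SD, n = 3) in WT and 12.6 ± 0.433 FPKM in Adrb3 KO. In the 3 Adrb2 KO libraries it was at 0.14, 0.03 and 0.14 FPKM, 0.855% of the WT mean. The 3 libraries were below all WT libraries (exact permutation p = 0.1, the smallest that 3 against 3 can give), as the genotype labels have it. Which part of the gene is deleted is not stated. Adrb3 was not analysed here, so the Adrb3 KO labels have no such check. The related receptor Adrb1 was below 0.3 FPKM in all 9 libraries.

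The first principal component, with 37% of the variance, set the 3 WT libraries apart from the 6 knockout libraries, and the second, with 19%, set Adrb3 KO apart from the rest. Pearson's r between libraries across genes was 0.986 to 0.992 within genotypes and 0.974 to 0.989 between them. By the F test of limma, 2200 of 12624 genes differed among genotypes. This count was 1054 without WT replicate 2, 1441 without Adrb2 KO replicate 2, 1432 without Adrb3 KO replicate 2 and 1224 with no filter on low values.

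**Figure D1:**
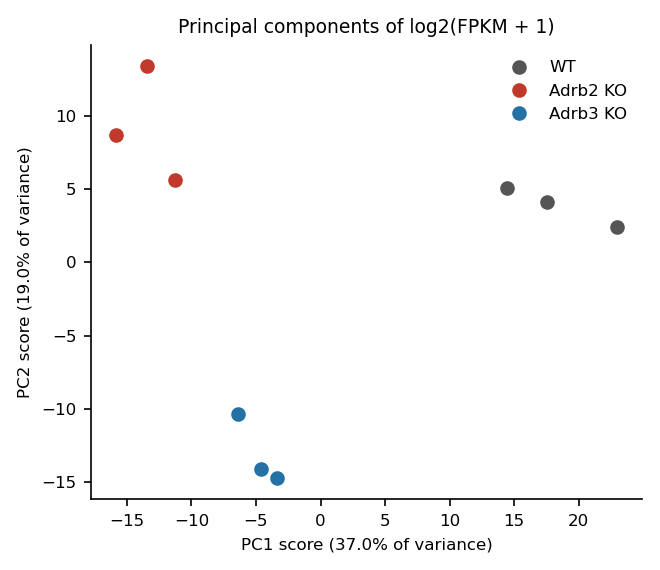
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1), coloured by genotype. WT libraries sit at 14.4 or higher on the first component and all knockout libraries at -3.35 or lower.

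Many genes of bone-forming cells (7 of 8 tested) and many immediate early genes (11 of 15) were lower in the marrow of Adrb2 KO mice than in that of WT mice, while many genes of early neutrophil granules (8 of 12) and plasma cells (8 of 12) were higher. None of these gene lists was called with an estimated correlation (adjusted p = 0.202, 0.222, 0.277 and 0.18). Osteocalcin (Bglap), a bone matrix protein of osteoblasts, was at 6.22 ± 3.33 FPKM in WT and 0.367 ± 0.0651 in Adrb2 KO, with a log2 fold change of -2.30 ± 0.26 (adjusted p = 0.000567). Fos, a transcription factor induced within minutes of stimulation, was at 50 ± 8.5 FPKM in WT and 12.6 ± 0.98 in Adrb2 KO. The inflammatory cytokine Il1b was at 50.8 ± 5.03 and 12 ± 1.09 FPKM. Jchain, which joins antibody chains in plasma cells, was at 59.5 ± 9.21 FPKM in WT and 155 ± 4.67 in Adrb2 KO.

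Of 12624 genes, 2651 passed the threshold in Adrb2 KO against WT, 1249 of them higher and 1402 lower. Most changes were small, with a median of 1.28-fold on the scale tested, and 99 genes changed at least 2-fold, of which 54 were immunoglobulin or T-cell receptor genes. The libraries of the 2 groups did not overlap for 35.7% of genes, where chance gives 10%. The split of directions depended on scaling, since values rescaled to the same total in every library gave 751 higher and 1492 lower, and the removal of a trend with transcript length and GC content, chosen after the data were seen, gave 1603 and 1189. The count was 1167 without WT replicate 2, 1421 without Adrb2 KO replicate 2, 1580 in a fit of the 2 groups alone and 1531 with no filter on low values. With no filter Cxcl12, Igkj4, Stab2 and the osteoclast list, all named below, lost their calls.

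Of 8 tested genes of osteoblasts and osteocytes, 7 fell, and all 8 did when adjusted over the list alone. Bglap2 fell from 5.55 ± 1.02 to 0.54 ± 0.219 FPKM and bone sialoprotein (Ibsp) from 9.25 ± 2.27 to 2.7 ± 0.527, and collagen Col1a1 had a log2 fold change of -1.25 ± 0.14. The list was called by camera (adjusted p = 7.15e-07), but not with an estimated correlation (adjusted p = 0.202). Of 9 tested genes of the mesenchymal niche, 4 fell and 1 rose, and the count was 6 lower and 1 higher when adjusted over the list alone. Among them Gas6 had a log2 fold change of -0.63 ± 0.10 and Esm1 of -0.61 ± 0.11. The niche list had an adjusted p of 0.02, which was 0.379 with an estimated correlation, and its call was lost without Adrb2 KO replicate 1 or WT replicate 3. All 4 tested skeletal muscle genes, each below 6 FPKM, also fell, with Tnni2 at 2.06 ± 0.0252 FPKM in WT and 1.33 ± 0.124 in Adrb2 KO. The muscle list was fixed because tissue around the bone could bring such genes. Whether the samples differed in the amount of such tissue was not tested. Of 7 osteoclast genes 4 fell, among them Nfatc1, the master transcription factor of these cells, while Atp6v0d2, a proton pump subunit, rose from 0.617 ± 0.219 to 2.06 ± 0.501 FPKM. The osteoclast list had an adjusted p of 0.0248 and of 0.229 with an estimated correlation. Of 7 endothelial genes 5 fell, led by Cdh5 and Stab2 (adjusted p = 0.0151, and 0.268 with an estimated correlation), with log2 fold changes of -0.37 ± 0.09 and -0.57 ± 0.14. The call of this list was lost without WT replicate 3, that of Cdh5 without WT replicate 2, and that of Stab2 without Adrb2 KO replicate 1, Adrb2 KO replicate 2 or WT replicate 2, or with the length and GC trend removed.

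Immediate early genes, which respond to signals without new protein synthesis, were lower in Adrb2 KO for 11 of 15 tested members, and 1 was higher. The counts were the same when adjusted over the list alone. Dusp1, a phosphatase of MAP kinases, fell from 24.2 ± 3.02 to 8.68 ± 0.0416 FPKM, Junb from 70.1 ± 3.76 to 43.3 ± 0.936 and Btg2 from 71.1 ± 1.93 to 44.6 ± 4.01. The higher one was the heat-shock gene Hspa1b, at 0.613 FPKM in WT and 1.57 in Adrb2 KO. Of the 8 tested genes of the cAMP and CREB response, the pathway downstream of beta receptors, 7 fell. Per1, at 3.55 ± 0.0833 FPKM in WT and 4.96 ± 0.391 in Adrb2 KO, rose. Fos, Dusp1 and Nr4a1 belong to both lists. Nr4a1 and Rgs2 had log2 fold changes of -0.56 ± 0.08 and -0.54 ± 0.08. Camera called both lists (adjusted p = 8.13e-06 and 2.48e-05), and neither with an estimated correlation (adjusted p = 0.222 and 0.18). In Adrb3 KO against WT 2 of the 8 cAMP and CREB genes were lower and 1 was higher (5 and 2 adjusted over the list alone). Camera did not call the list there (adjusted p = 0.119). Rgs2 was at 37.7 ± 2.85 FPKM in WT, 25.5 ± 2.14 in Adrb2 KO and 25.7 ± 1.87 in Adrb3 KO. Between the 2 knockouts 2 of the 8 differed.

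Among myeloid cells, genes of early neutrophil granules rose for 8 of 12 members, and none passed as lower. Adjusted over the list alone, 9 rose and 2 fell. Ms4a3, a marker of granulocyte and monocyte progenitors, rose from 64.4 ± 9.91 to 122 ± 7.68 FPKM, and proteinase 3 (Prtn3) from 263 ± 33.9 to 454 ± 39.5. Cathepsin G (Ctsg) rose from 217 ± 35.8 to 345 ± 27.3, and the chaperone Calr, also in the unfolded protein response list, from 222 ± 13.3 to 320 ± 16.7. Genes of mature neutrophils moved the other way for 8 of 16 members, and 1 rose. Ccl6 fell from 143 ± 6.64 to 77.4 ± 3.04 FPKM, and the receptor for granulocyte colony-stimulating factor (Csf3r) from 206 ± 26.2 to 111 ± 7.42. The early granule list had an adjusted p of 7.18e-05 and of 0.277 with an estimated correlation, and the mature neutrophil list of 0.00389 and 0.49. Olfm4, a gene of a neutrophil subset, rose from 35.1 ± 3.64 to 90 ± 3.15 FPKM. Its own list, the late granule genes, was not called, with 2 of 15 members higher.

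In Adrb2 KO 10 of 16 genes of tissue macrophages fell, and all 16 did when adjusted over the list alone. The macrophage marker Adgre1 (F4/80) fell from 23.4 ± 1.68 to 14.8 ± 1.44 FPKM, the iron exporter Slc40a1 from 33.6 ± 1.91 to 21.9 ± 3.4, and the receptor Axl from 48 ± 10.6 to 26.1 ± 4.09. Of 15 monocyte genes 6 fell, among them Cx3cr1, with a log2 fold change of -0.99 ± 0.08, and Csf1r, with -0.51 ± 0.07. Of 9 M1-type genes 6 fell, among them Il1b and Il18. Dendritic cell and antigen presentation genes fell for 5 of 14 members, with Cd209a at -1.01 ± 0.11. Camera called these 4 lists with adjusted p of 6.51e-07, 0.0207, 0.00269 and 0.0114, and with an estimated correlation the adjusted p was 0.306, 0.277, 0.277 and 0.379. The dendritic cell call was lost without WT replicate 3. Lower genes outside the lists were Cd101, a surface protein of myeloid cells (14.4 ± 2.81 to 3.46 ± 0.486 FPKM), and the lectin Cd209f (5.39 ± 1.05 to 0.997 ± 0.274). Of 14 genes of NF-kB and inflammation 5 fell and 1 rose, and the interleukin 1 antagonist Il1rn fell from 9.6 ± 0.599 to 5.74 ± 0.15 FPKM. Of 7 interleukins and growth factors of healing 3 fell, with Il1rn first and oncostatin M (Osm) next, at -0.51 ± 0.08. Of 16 genes of trafficking 6 fell and 1 rose, led by Cx3cr1 and Itgal, whose call was lost without WT replicate 2. These 3 lists had adjusted p of 0.00269, 0.00157 and 0.0151, and of 0.277, 0.18 and 0.413 with an estimated correlation.

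In the lymphoid lineage, plasma cell genes rose for 8 of 12 members (9 when adjusted over the list alone). Besides Jchain these included the heavy chain Igha, from 194 ± 19.1 to 315 ± 24.8 FPKM, and Derl3 and Txndc5, which serve protein folding and disposal in the endoplasmic reticulum. Of 268 tested immunoglobulin or T-cell receptor genes, 106 rose and 17 fell. Igkc rose from 1356 ± 68.3 to 2452 ± 85 FPKM, Ighm from 789 ± 50.1 to 1280 ± 40.2, Ighg3 from 2.24 ± 0.275 to 15.1 ± 1.75 and the joining segment Igkj1 from 207 ± 25.3 to 479 ± 25.7. Igkj4 rose from 99.5 ± 41.1 to 208 ± 39.7, a call lost without Adrb2 KO replicate 2 or 3. The split of reads among such similar genes is uncertain. B-cell precursor genes fell for 9 of 16 members, and for 12 when adjusted over the list alone. The surrogate light chain gene Igll1 fell from 13.9 ± 0.244 to 8.62 ± 0.627 FPKM, and Erg, Vpreb1 and Pax5 had log2 fold changes of -0.32, -0.61 and -0.47. Without Adrb2 KO replicate 2, Pax5 no longer passed. The plasma cell list had an adjusted p of 1.31e-06 and of 0.18 with an estimated correlation, and the precursor list of 2.98e-05 and 0.277.

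Red cell genes did not move as 1 group. Of 21 tested erythroid genes, 12 fell and 1 rose, and adjusted over the list alone 14 fell and 2 rose. The membrane protein Ermap fell from 21.5 ± 3.28 to 12.5 ± 1.03 FPKM, Hemgn from 34.3 ± 7.19 to 19.2 ± 2.06 and the transcription factor Gata1 from 15.8 ± 2.63 to 10.1 ± 0.426. The list had an adjusted p of 0.00157, and of 0.56 with an estimated correlation, and was not called by fry. Ribosomal protein genes rose for 28 of 47 members, and for 36 when adjusted over the list alone. Rps2 was at 416 ± 46 FPKM in WT and 615 ± 40.7 in Adrb2 KO, and Rpl34 at 81.5 ± 7.34 and 111 ± 6.89. These abundant short transcripts are also sensitive to RNA quality and to library preparation. Genes of the unfolded protein response rose for 12 of 16 members and fell for 2 (13 and 3 adjusted over the list alone). The chaperone Hspa5 rose from 113 ± 5.89 to 174 ± 10.2 FPKM and Creld2 from 24.6 ± 2.27 to 40.1 ± 0.575. Of 18 genes of hypoxia and glycolysis 7 rose, among them lactate dehydrogenase Ldha (167 ± 13.6 to 256 ± 10.4 FPKM) and Tpi1. Of 26 cell cycle genes 5 rose, led by Aurka and Cdk1, with log2 fold changes of 0.42 and 0.34, and the call of this list was lost under quantile normalization. The adjusted p of these 4 lists were 1.56e-13, 6.51e-07, 0.00461 and 0.000741, and with an estimated correlation 0.277, 0.18, 0.277 and 0.277. The remaining genes with the largest rises were the lipase Lipg (5.29 ± 0.232 to 17.4 ± 1.85 FPKM), matrix Gla protein Mgp (4.01 ± 1.64 to 12.1 ± 2.74) and Dmkn (2.88 ± 0.787 to 7.8 ± 1.52).

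**Figure D2:**
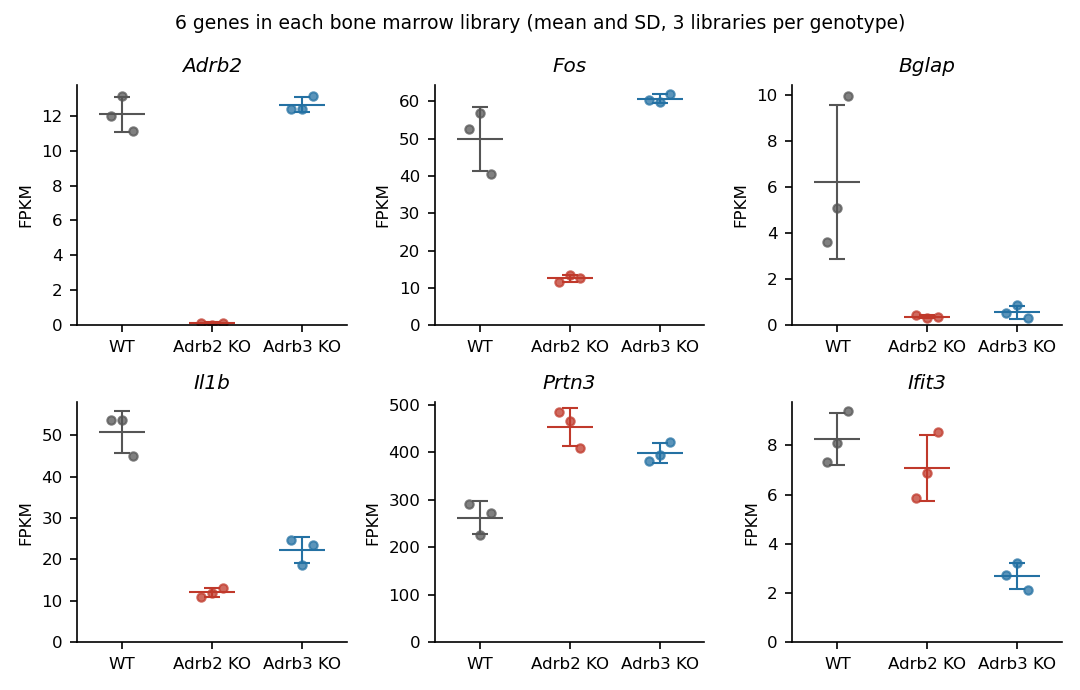
FPKM of 6 genes in each library (points), with the mean and SD of 3 libraries per genotype. Adrb2 is near 0 in the Adrb2 KO libraries, Fos is lower there than in both other genotypes, Bglap and Il1b are lower and Prtn3 is higher in both knockouts than in WT, and Ifit3 is lowest in Adrb3 KO.

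Many genes of the interferon response (15 of 20 tested), of tissue macrophages (13 of 16) and of B-cell precursors (12 of 16) were lower in the marrow of Adrb3 KO mice than in WT marrow, while many genes of plasma cells (9 of 12) and the unfolded protein response (11 of 16) were higher. None of these gene lists was called with an estimated correlation (adjusted p = 0.0697, 0.289, 0.132, 0.132 and 0.119). Ifit3, an antiviral gene induced by interferon, was at 8.26 ± 1.06 FPKM in WT and 2.7 ± 0.541 in Adrb3 KO, with a log2 fold change of -1.33 ± 0.14 (adjusted p = 0.00032). The macrophage receptor Siglec1 was at 9.02 ± 2.13 and 3.59 ± 0.376 FPKM. Vpreb1, a part of the pre-B-cell receptor, was at 17.5 ± 1.21 and 8.15 ± 0.87 FPKM. Jchain was at 59.5 ± 9.21 and 160 ± 19.9 FPKM.

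In this contrast 1226 of 12624 genes passed the threshold, 578 higher and 648 lower, with a median change of 1.33-fold. At least 2-fold changes were found for 103 genes, of which 63 were immunoglobulin or T-cell receptor genes, and libraries did not overlap for 32.7% of genes against 10% by chance. The count was 688, 579 and 609 without Adrb3 KO replicate 1, 2 and 3, and 620 without WT replicate 2. It was 1878 with library quality weights and 759 with no filter on low values. Of the genes named below, Spp1, Klrb1c, Tbx21, Siglech, Igkj4, Rps2, Rps28, Bub1 and Hbb-bt lost their calls with no filter.

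Interferon response genes fell for 15 of 20 members, and for 17 when adjusted over the list alone. Rtp4 fell from 12.6 ± 1.12 to 5.29 ± 0.366 FPKM, the transcription factor Irf7 from 17.8 ± 0.401 to 9.61 ± 0.696, Oasl2 from 11.4 ± 1.65 to 4.73 ± 0.307 and Oas1a from 23.4 ± 1.02 to 13.9 ± 1.02. The list was called by camera (adjusted p = 3.92e-18), but not with an estimated correlation (adjusted p = 0.0697). Tissue macrophage genes fell for 13 of 16 members, and for all 16 when adjusted over the list alone, with the phosphatidylserine receptor Timd4 at 2.47 ± 0.631 FPKM in WT and 0.547 ± 0.176 in Adrb3 KO and Axl at 48 ± 10.6 and 25.4 ± 1.3. Mature neutrophil genes fell for 7 of 16 members and 1 rose, with Il1b at 22.3 ± 3.12 FPKM in Adrb3 KO and log2 fold changes of -0.61 ± 0.07 for Ccl6 and -0.79 ± 0.10 for Csf3r. Of 15 monocyte genes 4 fell, led by Cx3cr1 and Csf1r, and of 9 M1-type genes 6 fell, led by Il1b and Il18. With an estimated correlation the adjusted p of these 4 lists was 0.289, 0.388, 0.142 and 0.199, after camera calls at 7.24e-12, 1e-06, 0.000694 and 2.24e-05. Dendritic cell genes fell for 2 of 14 members, Cd209a and Siglech, with an adjusted p of 0.02 and a call that was lost without WT replicate 2 or 3, with a mean of at least 5 FPKM and by fry. The adjusted p was 0.477 with an estimated correlation. Siglech itself was lost without any 1 of the Adrb3 KO libraries, WT replicate 2 or WT replicate 3. Cd209f fell from 5.39 ± 1.05 to 0.43 ± 0.0954 FPKM.

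B-cell precursor genes fell for 12 of 16 members, and for 15 when adjusted over the list alone. Igll1 fell from 13.9 ± 0.244 to 6.64 ± 0.332 FPKM, the recombinase Rag1 from 17 ± 0.642 to 9.23 ± 0.66 and Dntt from 20.9 ± 3.17 to 12 ± 0.916. Plasma cell genes rose for 9 of 12 members and 1 fell, with Igha at 194 ± 19.1 FPKM in WT and 421 ± 28.3 in Adrb3 KO and Ighg1 at 4.67 ± 0.0889 and 10.3 ± 1.16. Ighg2c had a log2 fold change of 1.52 ± 0.13. Of 268 tested immunoglobulin or T-cell receptor genes, 109 rose and 12 fell in this contrast. Ighg3 rose to 12.9 ± 1.44 FPKM, Igkc to 2695 ± 205, Igkj1 to 444 ± 30.9, Igkj2 to 464 ± 67.1 and Igkj4 to 252 ± 25.5, again with reads that similar genes may share. The adjusted p was 1.53e-12 for the precursor list and 3.95e-07 for the plasma cell list, and 0.132 for each with an estimated correlation. T and NK cell genes rose for 3 of 22 members (6 higher and 1 lower adjusted over the list alone), with Klrb1c, the NK1.1 antigen, at 0.38 ± 0.08 and Tbx21 at 0.32 ± 0.08. Klrb1c was lost without Adrb3 KO replicate 2 or 3, and Tbx21 without any 1 of the Adrb3 KO libraries or WT replicate 1 or 2. The list call (adjusted p = 0.0293) was lost without Adrb3 KO replicate 2, Adrb3 KO replicate 3 or WT replicate 1, with a mean of at least 5 FPKM, without immunoglobulin and T-cell receptor genes and by fry (adjusted p = 0.519 with an estimated correlation). In a fit of the 2 groups alone, or with the replicate number as a block, Tbx21 did not pass.

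Early granule genes rose for 6 of 12 members and 1 fell, led by Calr, Ms4a3 (64.4 ± 9.91 to 105 ± 1.93 FPKM) and Prtn3 (263 ± 33.9 to 399 ± 20.5). Calr also counts in the list of the unfolded protein response. Genes of the unfolded protein response rose for 11 of 16 members and 1 fell, with Hspa5 at 113 ± 5.89 FPKM in WT and 207 ± 8.43 in Adrb3 KO and Creld2 at 24.6 ± 2.27 and 48.9 ± 3.17. Ribosomal protein genes rose for 9 of 47 members, and for 25 when adjusted over the list alone, led by Rps2 and Rps28. Rps2 and Rps28 lost their calls without Adrb3 KO replicate 2 or 3. Rps28 also lost its call with the length and GC trend removed, and with the replicate block under median-of-ratios scaling. Of 26 cell cycle genes only Bub1 rose, and none did when adjusted over the list alone. Its call was lost without any 1 of the WT or Adrb3 KO libraries or Adrb2 KO replicate 2. The same held with libraries rescaled to the same total, with no variance trend, and with the replicate number as a block. Camera called these 4 lists with adjusted p of 0.00156, 7.49e-09, 1.86e-09 and 0.00729, and with an estimated correlation the adjusted p was 0.477, 0.119, 0.477 and 0.477. Without WT replicate 2 the cell cycle list was not called, and by fry neither it nor the ribosomal list was. Olfm4 rose to 88.1 ± 8.35 FPKM, Mgp to 26.1 ± 3.7 and the annotated microRNA locus Mir703 from 4.18 ± 1.98 to 10.6 ± 0.69. Hbb-bt, a beta globin, rose from 858 ± 325 to 1626 ± 257 FPKM at an adjusted p of 0.0482, a call lost without Adrb2 KO replicate 3, WT replicate 1, WT replicate 2 or any 1 of the Adrb3 KO libraries, and under median-of-ratios scaling, other variance models, a fit of the 2 groups alone and removal of the length and GC trend.

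Of 8 tested genes of osteoblasts and osteocytes, 3 fell and 1 rose (4 and 1 adjusted over the list alone). Bglap fell from 6.22 ± 3.33 to 0.56 ± 0.282 FPKM, Bglap2 from 5.55 ± 1.02 to 0.363 ± 0.19 and Col1a1 from 3.55 ± 1.06 to 1.49 ± 0.0751, while osteopontin (Spp1) rose from 18.8 ± 3.91 to 33.2 ± 2.87. The list had an adjusted p of 0.00249, and of 0.388 with an estimated correlation. Of 4 tested skeletal muscle genes 3 fell, with Tnni2 at 2.06 ± 0.0252 FPKM in WT and 1.21 ± 0.194 in Adrb3 KO. As above, tissue around the bone could bring such genes.

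Genes that differed between the 2 knockouts included 30 immunoglobulin or T-cell receptor genes higher and 43 lower in Adrb2 KO, 15 of 20 interferon response genes, 7 of 15 immediate early genes and 5 of 9 genes of the mesenchymal niche. Of these lists only the interferon response was called with an estimated correlation (adjusted p = 0.0207, 0.203 and 0.291). Fos was at 12.6 ± 0.98 FPKM in Adrb2 KO and 60.7 ± 1.19 in Adrb3 KO, a log2 fold change of -2.18 ± 0.11 (adjusted p = 5.45e-06). The chemokine Cxcl12, made by stromal cells that retain blood progenitors in marrow, was at 14.8 ± 2.13 and 36.9 ± 3.13 FPKM. Rtp4 was at 11.8 ± 0.72 FPKM in Adrb2 KO and 5.29 ± 0.366 in Adrb3 KO.

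In the direct contrast 298 genes passed the threshold, 114 higher and 184 lower in Adrb2 KO, and 51 changed at least 2-fold, 23 of them immunoglobulin or T-cell receptor genes. Values rescaled to the same total in every library gave 76 higher and 225 lower, and the removal of the length and GC trend gave 208 and 178. Libraries did not overlap for 25.7% of genes, against 10% by chance. The count was 178 without Adrb2 KO replicate 1, 172 without Adrb2 KO replicate 2, 155 without Adrb3 KO replicate 2 and 157 without Adrb3 KO replicate 3. With immunoglobulin and T-cell receptor genes left out, a setting chosen after the data were seen, it was 188. It was 192 with a mean of at least 5 FPKM and also 192 with no filter on low values. Of the results named below, Ibsp, Cd3e, Ermap, Rag1, Igll1, Raver1, Tomm6, Snora31, Ighg2c and the osteoclast list lost their calls with no filter.

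Interferon response genes were higher in Adrb2 KO than in Adrb3 KO for 15 of 20 members, and for 19 when adjusted over the list alone. Irf7 was at 16.9 ± 0.466 and 9.61 ± 0.696 FPKM, and Usp18 at 5.4 ± 0.28 and 2.75 ± 0.161. This list was called by camera (adjusted p = 7.98e-29) and also with an estimated correlation (adjusted p = 0.0207). It was the 1 list of the 3 contrasts for which that held. In Adrb2 KO against WT 2 of its 20 members were higher and 1 was lower. Further interferon-induced genes among the largest differences were Ifit3, Ifit3b, Isg15 (23.9 ± 2.13 and 13.2 ± 1.6 FPKM), Oasl1 and Ifi27l2a (91.2 ± 10.5 and 53.1 ± 3.73 FPKM). Fdx2 and Raver1, neighbours on chromosome 9, and Tomm6 were also higher. Without stated strand or multi-gene counting their values are uncertain, and Raver1 and Tomm6 lost their calls without Adrb2 KO replicate 1, Adrb2 KO replicate 3 or Adrb3 KO replicate 2, Raver1 also without Adrb3 KO replicate 3.

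Immediate early genes were lower in Adrb2 KO than in Adrb3 KO for 7 of 15 members, and for 9 when adjusted over the list alone. Dusp1 was at 8.68 ± 0.0416 and 24.7 ± 0.89 FPKM, Junb at 43.3 ± 0.936 and 77.8 ± 2.81 and Jun at 5.16 ± 0.21 and 8.83 ± 0.718. Of 8 cAMP and CREB response genes 2 were lower, Fos and Dusp1, and 5 when adjusted over the list alone. Mesenchymal niche genes were lower for 5 of 9 members, with Gas6 at 4.97 ± 0.357 and 9.14 ± 0.292 FPKM and the leptin receptor Lepr at 0.777 ± 0.111 and 2.32 ± 0.362. Genes of osteoblasts and osteocytes were lower for 3 of 8 members, with Spp1 at 14.5 ± 2.78 and 33.2 ± 2.87 FPKM and Ibsp at 2.7 ± 0.527 and 6.02 ± 0.526. Other genes of matrix and bone among the largest differences were the collagenase Mmp13 (0.783 ± 0.101 and 3.43 ± 0.86 FPKM) and the collagen Col6a1 (0.9 ± 0.0781 and 3.34 ± 0.494). Of 14 genes of NF-kB and inflammation 4 were lower, among them Cxcl2 (1.99 ± 0.675 and 8.23 ± 0.631 FPKM) and Il1b (12 ± 1.09 and 22.3 ± 3.12). These 5 lists were called by camera at adjusted p of 2.48e-09, 4.69e-05, 2.21e-05, 0.00018 and 0.00107. With an estimated correlation the adjusted p was 0.203, 0.203, 0.291, 0.3 and 0.321.

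T and NK cell genes were lower in Adrb2 KO than in Adrb3 KO for 3 of 22 members, with Cd8b1 at 4.57 ± 0.431 and 8.36 ± 0.22 FPKM and Cd3e at 1.27 ± 0.145 and 2.23 ± 0.208. Cd3e lost its call without Adrb2 KO replicate 1, Adrb2 KO replicate 2, Adrb3 KO replicate 2 or Adrb3 KO replicate 3. Of 21 erythroid genes 1 was lower, Ermap at 12.5 ± 1.03 and 19.8 ± 1.52 FPKM, and 16 were lower when adjusted over the list alone. Kel, the next by p, was at 7.92 ± 1.07 and 13.6 ± 2.16 FPKM with an adjusted p of 0.0524. Ermap was not called without Adrb2 KO replicate 2, Adrb3 KO replicate 2 or Adrb3 KO replicate 3. B-cell precursor genes were higher in Adrb2 KO for 2 of 16 members, Rag1 and Igll1, and for 7 when adjusted over the list alone. The call of Rag1 was lost without Adrb3 KO replicate 2. That of Igll1 was lost without Adrb2 KO replicate 2, Adrb2 KO replicate 3, Adrb3 KO replicate 2 or Adrb3 KO replicate 3. Igll1 also lost its call with libraries rescaled to the same total and with the replicate number as a block. By fry neither the erythroid list nor the precursor list was called. Camera called these 3 lists at adjusted p of 8.74e-06, 1.38e-07 and 2.21e-05, and with an estimated correlation the adjusted p was 0.291, 0.421 and 0.3. Camera also called early granule, late granule, ribosomal protein, hypoxia and osteoclast lists, in which no member passed the threshold by limma. Adjusted over the list alone, 4 osteoclast genes were lower. Calls of the early granule, late granule and ribosomal lists were lost without single libraries, the first without Adrb2 KO replicate 1 or 2, Adrb3 KO replicate 2 or WT replicate 3, the second without Adrb3 KO replicate 3 and the last without Adrb2 KO replicate 2. The calls of all 3 were also lost under quantile normalization and by fry, that of the hypoxia list by fry, and that of the early granule list under 5 further settings, namely a mean of at least 5 FPKM, libraries rescaled to the same total, globin genes left out, library quality weights and the length and GC trend removed. With an estimated correlation their adjusted p was 0.649, 0.542, 0.649, 0.348 and 0.203. Outside the lists Snora31 was lower, at 2.79 ± 0.921 and 9.14 ± 2.37 FPKM. Ighg2c was also lower, with a log2 fold change of -0.73 ± 0.13 and a call lost without Adrb2 KO replicate 2 or 3.

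**Figure D3:**
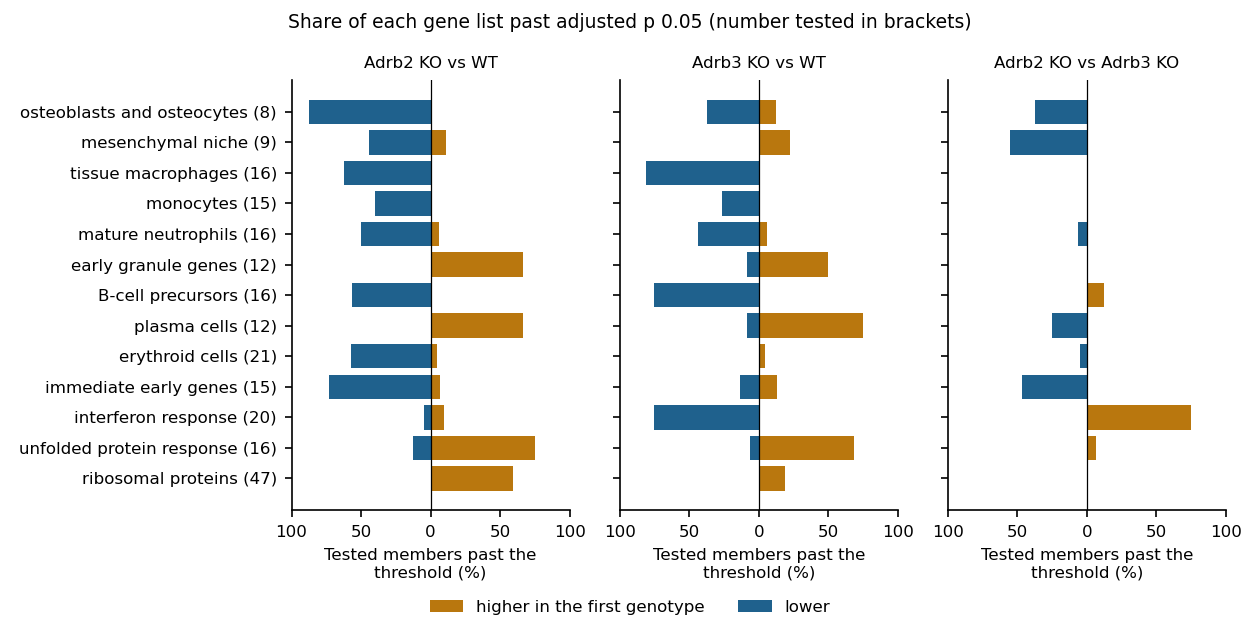
Percent of tested members of 13 gene lists that passed an adjusted p of 0.05, higher (right) or lower (left) in the first genotype named, for the 3 contrasts. Interferon response genes are lower in Adrb3 KO than in WT for 15 of 20 members and higher in Adrb2 KO than in Adrb3 KO for 15 of 20.

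Lists of stem and progenitor cells, M2-type genes, eosinophils with basophils and mast cells, megakaryocytes, mature B cells, adipocytes, the circadian clock and mitochondrially encoded genes were not called by camera in any of the 3 contrasts. By the test of fry for a shared direction, the M2-type list was lower in Adrb2 KO and in Adrb3 KO than in WT (adjusted p = 0.0145 and 0.00247), and the others were not called. Neither test looks for members of a list that move in opposite directions. Lists of adrenergic receptors, chondrocytes, skeletal muscle and sex-linked genes had fewer than 5 tested members and were not tested as lists. Among the sex-linked genes Xist was at 0.0267 FPKM in WT, 0.00667 in Adrb2 KO and 0.0367 in Adrb3 KO. The 4 tested ones were Ddx3y, Kdm5d, Uty and Eif2s3y. None of these 4 passed in either knockout against WT, and 1 was lower in Adrb2 KO than in Adrb3 KO. Members of the lists that camera did not call could still pass by themselves, among them Mrc1 and Cd163 of the M2-type list, at -1.06 ± 0.21 and -1.05 ± 0.18 in Adrb2 KO against WT. The numbers of lists called by camera were 22, 14 and 14 of 33, and 0, 0 and 1 with an estimated correlation.

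The fold changes of the 2 knockouts against WT went together. Of the genes past the threshold, 415 were higher in both knockouts and 465 lower in both, while 22 went in opposite directions. Independent lists of these sizes would share 57.2 and 72 genes. Across genes the log2 fold changes had a Pearson correlation of 0.70 and a covariance of 0.0512, against simulated means of 0.50 and 0.007. The covariance exceeded its simulated mean by 0.0442, in a simulation that drew each gene independently. Genes are not independent replicates. The 3 WT libraries were too few to split, and part of the excess overlap may come from them. The number shared in the same direction, 880, was 380 without WT replicate 2 and 497, 441 and 457 without Adrb3 KO replicate 1, 2 and 3, and 485 with no filter on low values. Genes that fell in Adrb2 KO and rose in Adrb3 KO included Cxcl12, with log2 fold changes of -0.67 and 0.59, and also Igfbp3 (-0.48 and 0.78) and Igfbp5 (-0.56 and 0.52), which were chosen after their values were seen. The fall of Cxcl12 lost its call without Adrb2 KO replicate 1, and its rise without Adrb2 KO replicate 2 or 3, any 1 of the Adrb3 KO libraries, or WT replicate 1 or 2. The fall of Igfbp3 lost its call without Adrb2 KO replicate 3 or WT replicate 3, and the rise of Igfbp5 without Adrb3 KO replicate 2, Adrb3 KO replicate 3 or WT replicate 2.

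**Figure D4:**
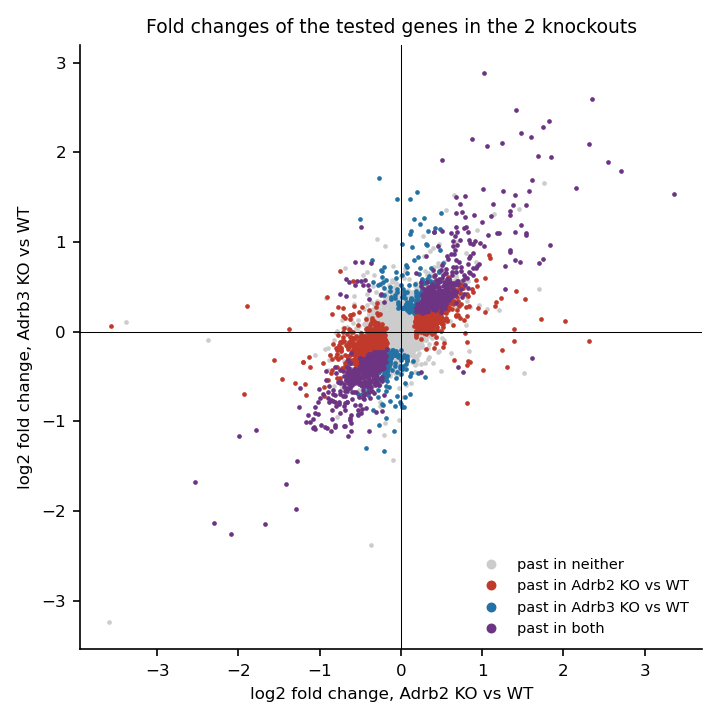
Log2 fold change of each tested gene in Adrb3 KO against WT (vertical) and in Adrb2 KO against WT (horizontal), coloured by the contrasts in which it passed an adjusted p of 0.05. Of the genes past in both, 880 lie in the quadrants of equal sign and 22 in the others.

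No excess of changed genes near the targeted genes was detected. On chromosome 18, which carries Adrb2, 20.3% of 271 tested genes passed in Adrb2 KO against WT, and 21.1% elsewhere (Fisher's exact test, p = 0.821). Within 10 Mb of Adrb2 it was 24.2% of 66 genes (Fisher's exact test, p = 0.544). On chromosome 8, which carries Adrb3 (27225776 to 27250616), 8.36% of 658 genes passed in Adrb3 KO against WT, and 9.81% elsewhere (Fisher's exact test, p = 0.25), with 7.69% of 78 genes within 10 Mb (Fisher's exact test, p = 0.701). The Benjamini-Hochberg adjusted value was 0.821 for each of these 4 tests. With 66 and 78 genes within 10 Mb, the tests could not detect changes of only a few flanking genes.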

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

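The settings without immunoglobulin and T-cell receptor genes and with the length and GC trend removed were chosen only after the data were seen. Across all settings, no named gene that passed in the main fit or in the setting reversed its direction. Where a result passed in neither, its direction was not compared. Of the values of named genes, 5696 stayed on their side of the threshold, 463 fell below it and 80 rose above it. For gene lists these numbers were 2381, 89 and 79, and by the same rule 1 list reversed. That was the ribosomal list in Adrb2 KO against Adrb3 KO under quantile normalization, with a median of 0 (adjusted p = 0.944), and the cause was not tested.

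Counts below are for Adrb2 KO against WT (2651 as reported), Adrb3 KO against WT (1226), Adrb2 KO against Adrb3 KO (298), any genotype (2200) and genes shared by both knockouts (880). With no filter on low values they were 1531, 759, 192, 1224 and 485, since more genes were tested. With a mean of at least 5 FPKM the direct contrast gave 192, since fewer were. Library quality weights gave 1878 for Adrb3 KO against WT, and a fit of the 2 compared groups alone gave 1580 for Adrb2 KO against WT. The cause was not tested. A 2-fold minimum gave 99, 103, 51 and 49 shared with adjusted p, and 106, 111, 61 and 52 shared with unadjusted p, as most changes were smaller. At an adjusted p under 0.1, Adrb3 KO against WT gave 1942, the direct contrast 554, any genotype 3528 and the shared genes 1434. The test of chromosome 8 then had a p of 0.0305 by Fisher's exact test, not adjusted for the other tests of position. The share of changed genes on chromosome 8 was lower than elsewhere, as in the main setting. Without immunoglobulin and T-cell receptor genes the direct contrast gave 188. Lists called with an estimated correlation were 0, 0 and 1. The log2 fold change of Adrb2, -3.57 on the scale tested, was -5.96 and -4.38 with 0.1 and 0.5 added in place of 1, -4.77 with libraries rescaled to the same total and -4.78 with globin genes also left out, since a smaller share of the added constant remained.

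With 1 library left out at a time, the counts ran from 1167 to 2617, 579 to 1337, 155 to 330, 1054 to 2143 and 380 to 976, with fewer libraries in each fit. The replicate number as a block gave 2381, 1073 and 290 genes, of which 2234, 974 and 241 were among those reported. No label says what a replicate number marks. Residuals of same-numbered libraries had correlations of -0.062 to 0.123, and the closest residuals had the same number in 10 of 18 comparisons, where chance gives 6, so not every library was closest to its own number. The camera test has no robust option, so that setting was not run for lists. Read depth is unknown, so what it limits was not measured.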

Other observations

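The tests of chaperones, clock genes, stromal genes, immunoglobulin segments, shared WT values, WT libraries prepared apart, and length and GC content were chosen only after the data were seen, and those of other splits were planned. Of 13 tested heat-shock chaperones, among them Hspa1b of the immediate early list, 8 were higher and 0 lower in Adrb2 KO against WT, and 10 were higher and 0 lower in Adrb3 KO against WT. Hsp90aa1 was at 83.6 ± 7.82 FPKM in WT, 125 ± 15.9 in Adrb2 KO and 151 ± 9.41 in Adrb3 KO, and Hspd1 at 72.3 ± 8.98, 109 ± 8.23 and 109 ± 2.95. The eosinophil chemokine receptor Ccr3 was at 9.73 ± 1.97 FPKM in WT, 4.11 ± 0.902 in Adrb2 KO and 4.07 ± 0.365 in Adrb3 KO, while the IgE receptor chain Fcer1a was at 6.36 ± 0.395, 9.4 ± 0.398 and 11 ± 2.24. Serpinh1, a collagen chaperone, was at 4.09 ± 0.819, 2.48 ± 0.248 and 6.49 ± 0.86 FPKM. It was chosen after its values were seen. Its rise in Adrb3 KO against WT lost its call without Adrb3 KO replicate 2, Adrb3 KO replicate 3 or WT replicate 2.

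Immunoglobulin variable segments differed between genotypes more often than other genes. By the F test of limma 140 of 199 segments passed (70.4%), against 2060 of 12425 other genes (16.6%). Igkv4-70 was at 5.35 ± 1.8 FPKM in WT, 62.4 ± 3.92 in Adrb2 KO and 17 ± 2.78 in Adrb3 KO, Igkv14-100 at 6.1 ± 0.336, 13.5 ± 1.44 and 51.9 ± 8.79, and Igkv1-122 at 6.17 ± 0.626, 34.6 ± 2.28 and 5.71 ± 0.74. Variation between libraries without a link to genotype was argued against, since the highest of 99 other groupings of the 9 libraries gave 61 segments. The libraries of a genotype may share animals or a marrow pool, which would carry the same antibody clones into each. Their SD within genotypes was 1.97 times that of other genes of the same level, and between genotypes 4.64 times. Shared animals and a difference by genotype cannot be told apart, because the labels do not say which animals gave each library. If libraries were shared in this way, every p-value here would measure preparation and not animals.

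Of 15 tested immediate early genes, 11 were lower and 1 was higher in Adrb2 KO than in WT, and 7 were lower and 0 higher than in Adrb3 KO. The list was called in neither contrast with an estimated correlation (adjusted p = 0.222 and 0.203). Rough or delayed handling of WT tissue may raise such genes, and may raise heat-shock chaperones too. The median log2 fold change of the chaperones was 0.28 in Adrb2 KO against WT, the other way. In Adrb3 KO against WT it was 0.419, while that of the immediate early genes was -0.036. The chaperones thus moved there without the immediate early genes, so they cannot decide on handling. For Adrb2 KO against Adrb3 KO the chaperone median was -0.148, with 1 lower and 0 higher of 13. Handling stays open in both comparisons. Collection at different hours of the day also stays open, and intervals of clock genes were taken only between the 2 knockouts. Against WT, 1 of 13 tested clock genes was higher and 2 were lower in Adrb2 KO. In Adrb3 KO 1 was higher and 1 lower than in WT, so different hours stay open there too. In Adrb2 KO against Adrb3 KO, the 95% intervals of 10 of 13 clock genes excluded a 2-fold difference of FPKM, but those of Nr1d1, Nr1d2 and Dbp did not. The intervals of these 3 and of Clock excluded 0, with log2 fold changes of -0.27, -0.42, -0.34 and -0.24, and none passed an adjusted p of 0.05 (0.208, 0.119, 0.166 and 0.244). A smaller share of stromal cells cannot be told apart from lower expression per cell. The median of 17 niche and osteoblast genes minus that of 15 immediate early genes was -0.275 against WT (95% interval -0.608 to 0.286 over 10000 resamples of the list members). Against Adrb3 KO it was -0.218 (-0.581 to 0.335). These intervals do not measure the spread between libraries. Of the niche genes, Hp and Vcam1 also belong to the late granule and tissue macrophage lists. Loss of beta 2 signalling, the difference that the design names, also stays open.

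Both knockouts shifted the same way against WT. The covariance of the 2 sets of fold changes was 0.0512, against at most 0.0083 in 100 simulated pairs of unchanged groups. Each gene was simulated independently, with the spread seen within genotypes. The comparison argues against independent chance values of that size in the shared WT libraries. It cannot decide on noise that genes share or on differences between animals. Fold changes against WT followed transcript length in part, with Spearman's rho of -0.272 in Adrb2 KO and -0.159 in Adrb3 KO. Their rho with GC content was -0.042 and -0.24. Transcript length and GC content were argued against as the whole cause, since 677 of 870 shared genes with a known length remained shared after that trend was removed. WT libraries collected or prepared apart from both knockouts cannot be told apart from an effect of losing either receptor, because no label gives a batch. The first principal component, with 37% of the variance, sets WT apart in either case.

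Other splits of the libraries were also counted. In each contrast only 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, with 2651, 1226 and 298 genes and at most 1, 0 and 1 in other splits. With 10 splits the share cannot fall below 0.1. For any genotype 1 of 100 groupings, the real one, gave as many as 2200 genes, and the highest other gave 768. This argues against variation between libraries without a link to genotype. Chance differences between animals are not excluded by it, since the libraries of a genotype may share animals. For gene lists called, 1, 2 and 1 of 10 splits gave as many, with 22, 14 and 14 lists in the real split and 16, 15 and 13 in the highest other. Many lists were thus called in splits that mix genotypes.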
